A study of Homo sapiens with 13 samples.

How the data were processed

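The series profiled short RNA fragments that stayed bound to tagged splicing proteins in 293Flp-In cells, a derivative of the human embryonic kidney line HEK293 built to carry a transgene at a fixed genomic site. The cells expressed RBM5, RBM10 or SF3A3 with a Flag tag. Per the labels' protocols, nuclear extract of high molecular weight was released with nucleases and the protein-bound RNA was recovered on anti-Flag beads. In RNP-seq the extract was first sedimented and gradient fractions 11 to 13 were used, and in IP-seq the extract went straight to the beads. U2 snRNA was destroyed with an antisense oligonucleotide and RNase H, and fragments of 28 to 55 nt were sequenced. Per the labels' protocols each read carries random bases that serve to remove PCR duplicates. Whether that was done is not given in the sources used here.

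The authors deposited 1 table of RPKM values for 385655 clusters in 12 libraries, and 4 lists of predicted branch points. RPKM is reads per kilobase of cluster and per 1000000 reads of the library, per the file headers. Coordinates are on hg19, per the submitters' processing notes, which also name cutadapt and Bowtie2 without a role or version. How clusters were found, from which libraries, and how reads mapping to several places were treated is not given in the sources used here. Clusters carry a class in their deposited names: 145893 are marked 3'ss, 7060 are marked 5'ss and 232702 carry no mark and are called unclassed here. The marks are read as 3' and 5' splice site, and the distance or annotation behind them is not stated. In the deposited lists each predicted branch point has a position and a rank within its cluster, a score from 1 (best) per the file headers, and no measure of support. The lists are named for RBM5, for RBM10 and, in 2 lists, for SF3A3. None names a library or assay, so the SF3A3 lists are called first and second in file order.

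Libraries were grouped by their titles into RBM5 RNP-seq, SF3A3 RNP-seq, RBM10 IP-seq and SF3A3 IP-seq, with 3 libraries each. For SF3A3 IP-seq replicate 1 another label names the gradient fractions, while its title and treatment name the direct extract, and the title was followed. A 13th library, RBM5 RNP-seq without removal of U2 and with inserts of 25 to 80 nt, has no column in the table and is not analysed here. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No library from an untagged line or from input RNA is among the samples, so levels could be set only against SF3A3.

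RPKM multiplied by cluster width fell on whole multiples of 1 step in each library, within 0.05 reads for 100% of values. That gave the whole reads per cluster and the library total behind each RPKM value. Totals ran from 23834859 to 35509705 reads in RNP-seq and from 5868278 to 18960560 in IP-seq. At the median cluster width 1 read is worth 0.655 to 0.976 RPKM in RNP-seq and 1.23 to 3.96 RPKM in IP-seq. No pair of libraries of a group agreed within sampling noise: chi-square per degree of freedom ran from 1.32 to 3.73. It was taken over clusters with at least 20 reads summed over the pair.

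The test was fixed before the data were examined: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(RPKM + 1), over all 12 libraries, which share 1 estimate of the spread with 8 residual degrees of freedom. Clusters above 0 in all 3 libraries of at least 1 group were tested, which left 383238. Tests were two-sided, and a cluster was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale, where the change of a cluster with few reads depends on the pseudocount and can be understated or, where some libraries hold 0 reads, overstated. The comparisons were RBM5 against SF3A3 in RNP-seq, RBM10 against SF3A3 in IP-seq, SF3A3 RNP-seq against SF3A3 IP-seq, and the difference between the first 2 as an interaction. Class shares were compared by exact permutation tests of 3 against 3 libraries, whose smallest possible two-sided p is 0.1. Intervals for ratios of reads and shares of branch points are exact binomial 95% intervals. They cover counting error only, since reads made by PCR are not independent molecules. Where a group had 0 reads at a cluster, the fold is a lower bound at 3 reads over the group.

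The test was tried on simulated negative binomial reads with the real mean levels, library totals and each group's spread, with known changes in RBM5 or RBM10. With 20 percent of 383238 clusters changed and RBM5 as the changed group, 26.7% of 2-fold, 53.6% of 4-fold and 75.9% of 8-fold changes were recovered and 0.1% of calls were false. With RBM10 as the changed group the recovered shares were 33.2%, 63.1% and 77.4%, but 13.7% of calls were false, above the 5 percent aimed at. With 200 clusters changed, 45.0% of the 100 RBM10 calls were false. The RBM10 libraries varied most (dispersion 0.0499, against 0.0102 to 0.0218 in the other groups). With equal dispersion in all groups 29.0% of 69 RBM10 calls were still false, so unequal dispersion was not the whole cause. With limma voom on the whole reads, false calls among 20 percent changed clusters came to 2.7% for RBM5 and 5.2% for RBM10. With only the groups compared in the fit they came to 3.1% and 4.3%. Counts from both fits are therefore given beside the planned test's total and class counts for RBM5 and RBM10.

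Clusters named in the text follow a rule: an adjusted p under 0.05, an absolute log2 fold change of at least 1, no overlap between the libraries of both groups, and a mean RPKM at or above the median, then the 10 largest changes per direction. Parts of the rule that needed gene names could not be applied. All 10 of the largest RBM5 increases by the rule lay in clusters of 16 to 21 nt, shorter than the shortest fragment sequenced, so the same rule was applied again to clusters of at least 28 nt, overall and per class. That addition was chosen after the data were seen, and unless the text says otherwise the clusters named come from it.

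Gene names were not assigned. The files hold none, and the gene table at hand is on GRCh38.p14, another build than the clusters, so its coordinates were not used. Planned tests on gene totals and gene lists were therefore not run. Alternatives tried were other pseudocounts and filters, median-ratio and quantile scaling, a fit of only the groups compared, no intensity trend, the replicate number as a block, a fold threshold, and leaving out each library in turn. The voom fit, the width limit and quantile scaling of class medians were added after the data were seen. Tables and figures outside R were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.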

Results

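During assembly of the spliceosome, after the U1 snRNP has recognised the 5' splice site, the U2 snRNP joins at the branch site, the stretch upstream of the 3' splice site that holds the branch point. SF3A3 is a core protein of the U2 snRNP. RBM5 and RBM10 are related RNA-binding proteins that regulate exon choice. The libraries hold RNA fragments protected in complexes purified through Flag-tagged SF3A3, RBM5 or RBM10 from 293Flp-In cells. Comparing each RBM protein with SF3A3, under the same purification, asks at which clusters the RBM complexes hold more or less RNA than SF3A3 complexes do. RBM5 and SF3A3 were profiled by RNP-seq and RBM10 and SF3A3 by IP-seq, with 3 libraries in each of the 4 groups.

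Depth differed between groups. The RBM5 RNP-seq libraries held 28191728, 34705552 and 35509705 reads and the SF3A3 RNP-seq libraries 32138048, 26358789 and 23834859. The IP-seq libraries were shallower, at 5868278, 18960560 and 10033482 reads for RBM10 and 10624697, 9023319 and 6923340 for SF3A3. Of all reads, 81.5 to 81.8% fell in clusters with RBM5, 88.2 to 88.8% with SF3A3 RNP-seq, 83.3 to 86.4% with RBM10 and 89.7 to 90.7% with SF3A3 IP-seq. In every library most cluster reads lay in clusters marked as 3' splice sites, where branch sites are found. Their mean share was 68.8% ± 0.75 (SD, n = 3) with RBM5, 73.2% ± 0.09 with SF3A3 RNP-seq, 69.3% ± 0.65 with RBM10 and 71.0% ± 0.96 with SF3A3 IP-seq.

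By share of cluster reads, RBM5 libraries held more RNA from 5' splice site clusters and less from 3' splice site clusters than SF3A3 RNP-seq libraries did. The 5' splice site share of cluster reads was 0.269% ± 0.023 (SD, n = 3) with RBM5 and 0.123% ± 0.002 with SF3A3 RNP-seq, a ratio of 2.19. Of 6565 tested 5' splice site clusters, 758 (11.55%) were higher and 56 (0.85%) lower with RBM5, against 10.3% and 11.57% of all clusters. The share higher was near that of all clusters. Most 5' splice site clusters were dim: 2751 and 1411 lay in the 2 dimmest of 10 equal bins of SF3A3 replicate 1 level, at 1.79 RPKM or lower. Such levels leave little room for a decrease. Among the 1206 at or above the median mean RPKM, 402 (33.3%) were higher and 40 lower. Of 76027 unclassed clusters that bright, 15095 (19.9%) were higher and 11435 lower. Of 145755 tested 3' splice site clusters, 14512 were higher and 30859 lower. Among 230918 unclassed clusters 24219 were higher and 13422 lower, but 23299 and 23855 under quantile normalization. Their share of reads was 31.0% ± 0.72 with RBM5 and 26.7% ± 0.08 with SF3A3. The median log2 fold change of unclassed clusters exceeded that of 3' splice site clusters by 0.65 among all clusters, but by 0.04 among clusters of matched SF3A3 level and by 0.52 among clusters of matched RBM5 level. The median log2 fold change of 5' splice site clusters was 0.55, close to the 0.52 of unclassed clusters. It was -0.13 for 3' splice site clusters and 0.28 for all clusters. The medians also fell with level. From the dimmest to the brightest of 10 equal bins of mean RPKM, they went from 0.899 to -0.373 at 3' splice site clusters and from 0.965 to -0.297 at unclassed clusters. Under quantile normalization the 5' splice site median turned to -0.01, where that of unclassed clusters was 0.15 and that of all clusters 0.03. The RBM5 and SF3A3 libraries did not overlap in any of the 3 class shares, and the exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow.

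These class counts depended on the fit and on single libraries. With only the RNP-seq libraries in the fit, 1857 5' splice site clusters were higher and 136 lower, 28056 and 46650 at 3' splice sites, and 59454 and 24763 unclassed. With voom they were 1736 and 128, 26070 and 44245, and 56249 and 23318. Higher counts were 395 (5' splice site), 9480 (3' splice site) and 14855 (unclassed) without RBM5 replicate 1. Without RBM5 replicate 2, SF3A3 replicate 2 and SF3A3 replicate 3 they were 399, 478 and 414 at 5' splice sites and 14528, 16095 and 15151 unclassed. Without any 1 of the 6 libraries, 26 to 36 5' splice site clusters were lower.

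Single clusters differed by far more than the class averages. A 3' splice site cluster on chromosome 17 (60351539 to 60351582, minus strand) stood at 648 ± 79.8 RPKM (SD, n = 3) with RBM5 and 0.759 ± 0.713 RPKM with SF3A3 RNP-seq, with 2777 reads against 3. Its log2 fold change was 8.61 ± 0.60 (SE, limma adjusted p = 4.42e-08). Another on the same strand (58094900 to 58094931) stood at 867 ± 147 against 2.71 ± 0.81 RPKM, and an unclassed cluster (34590471 to 34590521) at 604 ± 82.5 against 6.34 ± 2.41 RPKM. A further unclassed cluster on chromosome 11 (133805259 to 133805299, minus strand) had 362 reads with RBM5 and 1 with SF3A3. The 5' splice site cluster that rose most lay on chromosome 12 (56646769 to 56646836, minus strand), at 427 ± 105 RPKM with RBM5 and 8.50 ± 3.10 with SF3A3, a log2 fold change of 5.52 ± 0.33 (limma adjusted p = 9.52e-09). A 5' splice site cluster on chromosome 17 (26965526 to 26965574, minus strand) stood at 112 ± 18.8 against 5.11 ± 1.48 RPKM. With RBM10 the levels of these 5' splice site clusters were 39.1 ± 14.7 and 26.5 ± 5.62 RPKM, against 38.2 ± 8.01 and 9.74 ± 4.36 with SF3A3 IP-seq.

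In the other direction, an unclassed cluster on chromosome 19 (53394608 to 53394656, minus strand) held 247 ± 20.9 RPKM with SF3A3 RNP-seq and 0.383 ± 0.664 RPKM with RBM5. Its log2 fold change was -7.58 ± 0.47 (SE, limma adjusted p = 1.37e-08). A 3' splice site cluster on chromosome 14 (23587050 to 23587085, minus strand) held 848 ± 194 against 6.73 ± 1.81 RPKM. A 3' splice site cluster on chromosome 4 (23769897 to 23769931, plus strand) had 309 reads in the SF3A3 libraries and 0 in the RBM5 libraries, at least 123-fold lower with RBM5. An unclassed cluster on chromosome 13 (51600967 to 51601002, minus strand) held 186 ± 23.2 against 0.918 ± 0.992 RPKM.

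Across all 383238 tested clusters, 39489 were higher and 44337 lower with RBM5 than with SF3A3. Fitting only the 6 RNP-seq libraries raised the total from 83826 to 160916, and the voom fit raised it to 151746, of which 83750 were called in the same direction by the planned test. The balance of directions turned in both fits, to 89367 higher and 71549 lower and to 84055 higher and 67691 lower, and was near even with median-ratio scaling (43503 and 43199). The higher count was 24730 without RBM5 replicate 1, 24794 without RBM5 replicate 2 and 25392 without SF3A3 replicate 3. Clusters under 28 nt, shorter than the shortest fragment sequenced, have an origin that these values do not settle, whether partial alignments, a short contaminating RNA or an edge of cluster calling. They took 1.01% ± 0.19 (SD, n = 3) of cluster reads with RBM5 and 0.084% ± 0.003 with SF3A3 RNP-seq, 0.095% ± 0.007 with RBM10 and 0.043% ± 0.004 with SF3A3 IP-seq. Without that width limit, the rule's largest increase was an unclassed cluster of 17 nt on chromosome 15 (63989485 to 63989501, plus strand) with 19487 reads with RBM5 and 0 with SF3A3 RNP-seq.

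**Figure D1:**
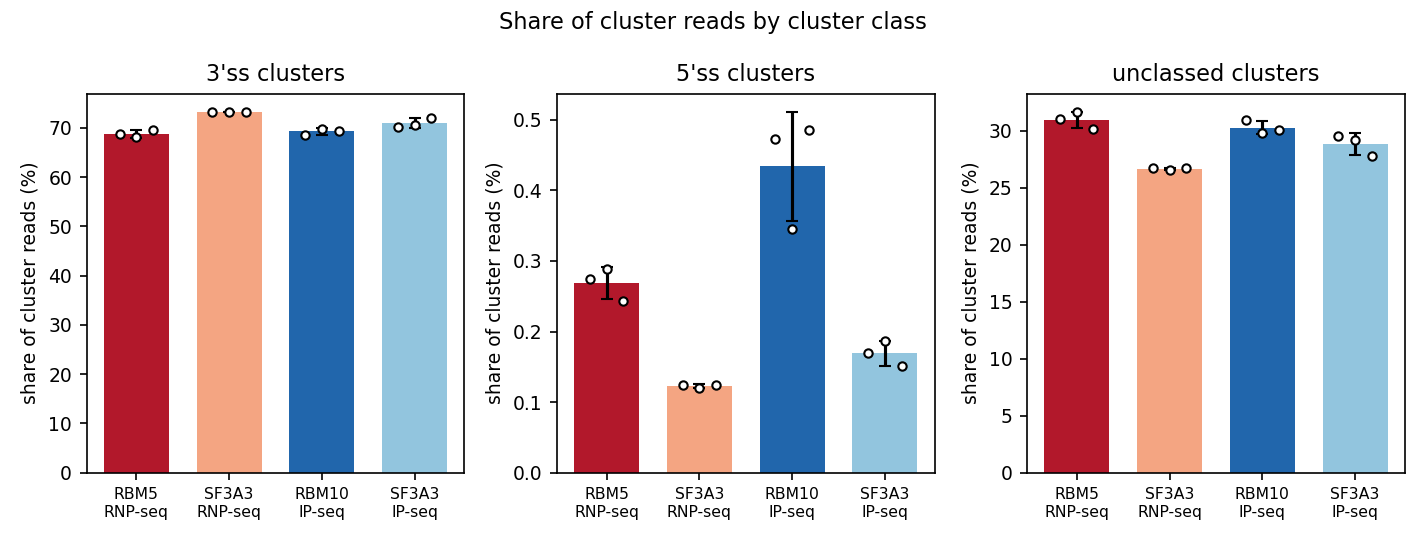
Share of cluster reads (percent, y axis) in clusters marked 3'ss, clusters marked 5'ss and unclassed clusters, for the 4 groups of libraries. Bars are means of 3 libraries, error bars are SDs and circles are single libraries. The 5'ss share was 0.269% with RBM5 against 0.123% with SF3A3 RNP-seq, and 0.434% with RBM10 against 0.169% with SF3A3 IP-seq.

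RBM10 complexes differed from SF3A3 complexes most clearly at 5' splice sites. Of the 6565 tested 5' splice site clusters 2872 (43.7%) were higher with RBM10 and 88 lower. With voom the counts were 2378 and 70, and with only the IP-seq libraries in the fit 734 and 31. Without RBM10 replicate 2 the lower count was 134. The median log2 fold change was 1.67, and 0.91 among the 1206 clusters at or above the median mean RPKM, where 443 were higher and 70 lower. The 5' splice site share of cluster reads was 0.434% ± 0.077 (SD, n = 3) with RBM10 and 0.169% ± 0.018 with SF3A3 IP-seq, a ratio of 2.57. The difference of 0.265 points fell to 0.074 among those brighter clusters. At 3' splice site clusters 18834 were higher and 25267 lower, with a median of -0.05 (0.01 without RBM10 replicate 1). At unclassed clusters 20409 were higher and 13979 lower, with a median of 0.13, which went to 0.00 under quantile normalization (-0.002) and without RBM10 replicate 2. That median was 0.02 without SF3A3 IP-seq replicate 3, 0.20 without SF3A3 IP-seq replicate 1 and 0.24 without RBM10 replicate 1. With only the IP-seq libraries in the fit the counts were 5906 and 8424 at 3' splice sites, and 5426 and 4245 unclassed. With voom they were 13379 and 18743, and 14565 and 10430. The RBM10 and SF3A3 libraries did not overlap in any class share (exact two-sided permutation p = 0.1 for each, the smallest possible).

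The gains with RBM10 at 5' splice sites were spread over many dim clusters. The top pair by the rule lay on chromosome 1. One (97243491 to 97243521, plus strand) had 64 reads over the RBM10 libraries and 0 over the SF3A3 IP-seq libraries, at least 16.3-fold higher (limma adjusted p = 1.34e-05). The other (28834661 to 28834696, plus strand) had 67 reads against 0, at least 17.0-fold higher. Both were near the floor in RNP-seq, at 0.381 ± 0.661 and 0.856 ± 0.112 RPKM with RBM5.

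Elsewhere, unclassed clusters on chromosome 14 (52190858 to 52190898, plus strand) and chromosome 8 (54827323 to 54827356, plus strand) had 361 and 265 reads with RBM10 and 0 with SF3A3 IP-seq, at least 91.7-fold and 67.3-fold higher. An unclassed cluster on chromosome 16 (21653416 to 21653453, plus strand) held 1982 ± 1358 RPKM with RBM10 and 8.22 ± 2.87 with SF3A3 IP-seq, a log2 fold change of 7.59 ± 0.32 (SE, limma adjusted p = 3.15e-09). The same cluster held 415 ± 29.0 RPKM with SF3A3 in RNP-seq. Lower with RBM10 were the clusters on chromosome 13 (51600967 to 51601002) and chromosome 19 (53394608 to 53394656) that were also lower with RBM5, at 2.93 ± 5.07 and 1.75 ± 1.63 RPKM against 221 ± 22.4 and 159 ± 8.94. A 3' splice site cluster on chromosome 1 (70503748 to 70503780, plus strand) had 0 reads with RBM10 and 81 with SF3A3 IP-seq, at least 35.4-fold lower. A 3' splice site cluster on chromosome 15 (97974973 to 97975012, plus strand) held 10.1 ± 8.94 against 454 ± 83.4 RPKM.

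In all, 42115 clusters were higher and 39334 lower with RBM10. This total of 81449 fell to 24766 when only the 6 IP-seq libraries entered the fit and to 59565 with voom, of which 57934 were called in the same direction by the planned test. The balance turned with only the IP-seq libraries (12066 higher, 12700 lower), under quantile normalization (36792, 39565) and without RBM10 replicate 2 (39482, 47566). In simulated data with these depths, 13.7% of the planned test's RBM10 calls were false with 20 percent of clusters changed and 45.0% with 200 clusters changed. The false share among the real calls depends on how many clusters truly differ, which is not known.

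**Figure D2:**
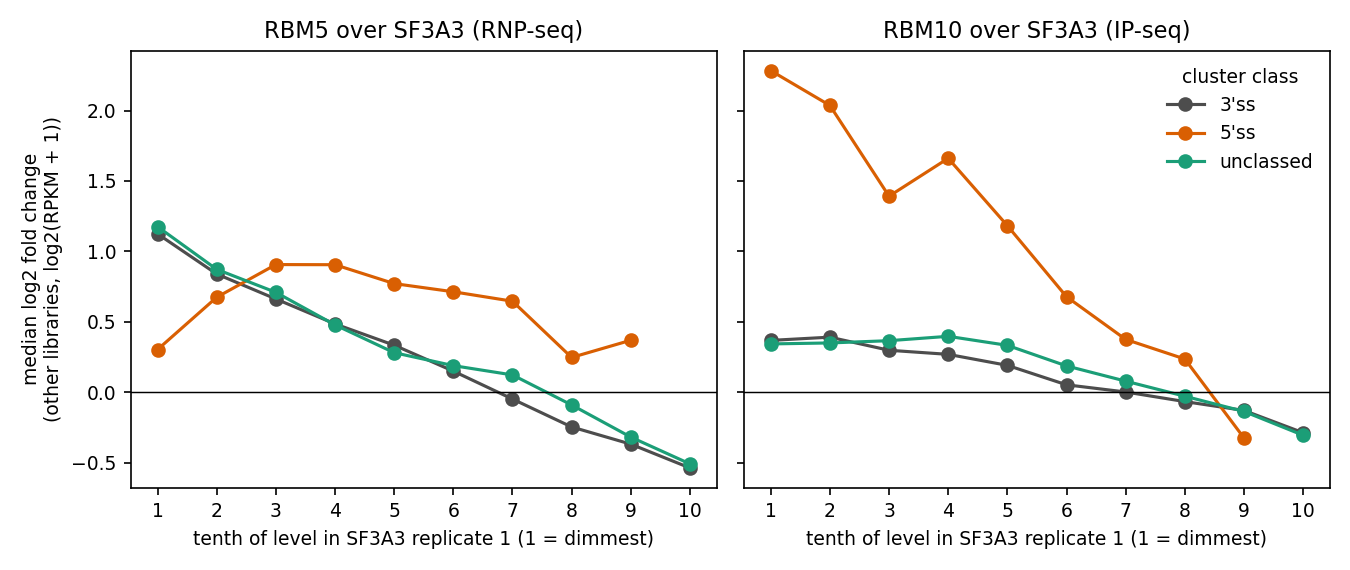
Median log2 fold change (y axis, log2(RPKM + 1) scale) of RBM5 over SF3A3 and of RBM10 over SF3A3 against 10 equal bins of cluster level in SF3A3 replicate 1 (x axis, 1 is dimmest), for each class with at least 20 clusters in the bin. SF3A3 replicate 1 set the bins and was left out of the fold change. With RBM10 the 5'ss median lay above the unclassed median in 8 of 9 bins and with RBM5 in 7 of 9. The RBM5 exceptions were bins 1 and 2, which held 2751 and 1411 of the 6565 tested 5'ss clusters and so most of them.

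The clusters that changed with RBM5 and with RBM10 overlapped in part. No library is common to both comparisons, but both use the same estimate of spread from all 12 libraries. The counts for independent lists given here do not allow for that. Fold changes over SF3A3 correlated weakly across the 383238 clusters (Pearson r = 0.119, Spearman rho = 0.131; clusters are not independent replicates). Clusters lower with both proteins numbered 11433, against 4551 for independent lists and 9823 for lists independent within narrow ranges of level. Clusters higher with both numbered 5737, against 4340 and 4714. Clusters higher with RBM5 and lower with RBM10 numbered 3838, against 4053 and 5372. Clusters lower with RBM5 and higher with RBM10 numbered 7273, against 4872 and 7249. The clusters on chromosomes 13 and 19 named above were among the 4 largest decreases with each protein among clusters of at least 28 nt. Without that limit they ranked 10th and 4th with RBM5.

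The RBM5 effect differed from the RBM10 effect at 71130 clusters, 33904 with the larger log2 fold change for RBM5 and 37226 with the larger for RBM10. This balance turned with voom (44790 and 40410), with median-ratio scaling (37048 and 35427) and without RBM10 replicate 2 (43116 and 36705). This compares the proteins together with their purifications, since each was profiled by a different assay, with SF3A3 as the reference in both. At 5' splice site clusters 286 were relatively higher with RBM5 and 1358 relatively higher with RBM10, but 183 and 152 among clusters at or above the median mean RPKM. The counts were 178 and 902 without RBM5 replicate 1 and 179 and 955 without RBM5 replicate 2. The 5' splice site share rose over SF3A3 by 1.13 on the log2 scale with RBM5 and by 1.35 with RBM10. An exact permutation test of the difference over 400 arrangements gave p = 0.7 (Benjamini-Hochberg p = 0.7 over 3 classes). These arrangements remove the effects of both proteins and not only their difference, so the test cannot decide whether the rises differ. A 5' splice site cluster on chromosome 7 (100281159 to 100281197, minus strand) went opposite ways. It held 699 ± 99 RPKM with RBM5 against 73.0 ± 3.37 with SF3A3 RNP-seq, and 9.42 ± 6.12 with RBM10 against 206 ± 49.9 with SF3A3 IP-seq. The interaction was 7.69 ± 0.43 on the log2 scale (SE, limma adjusted p = 2.31e-08).

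**Figure D3:**
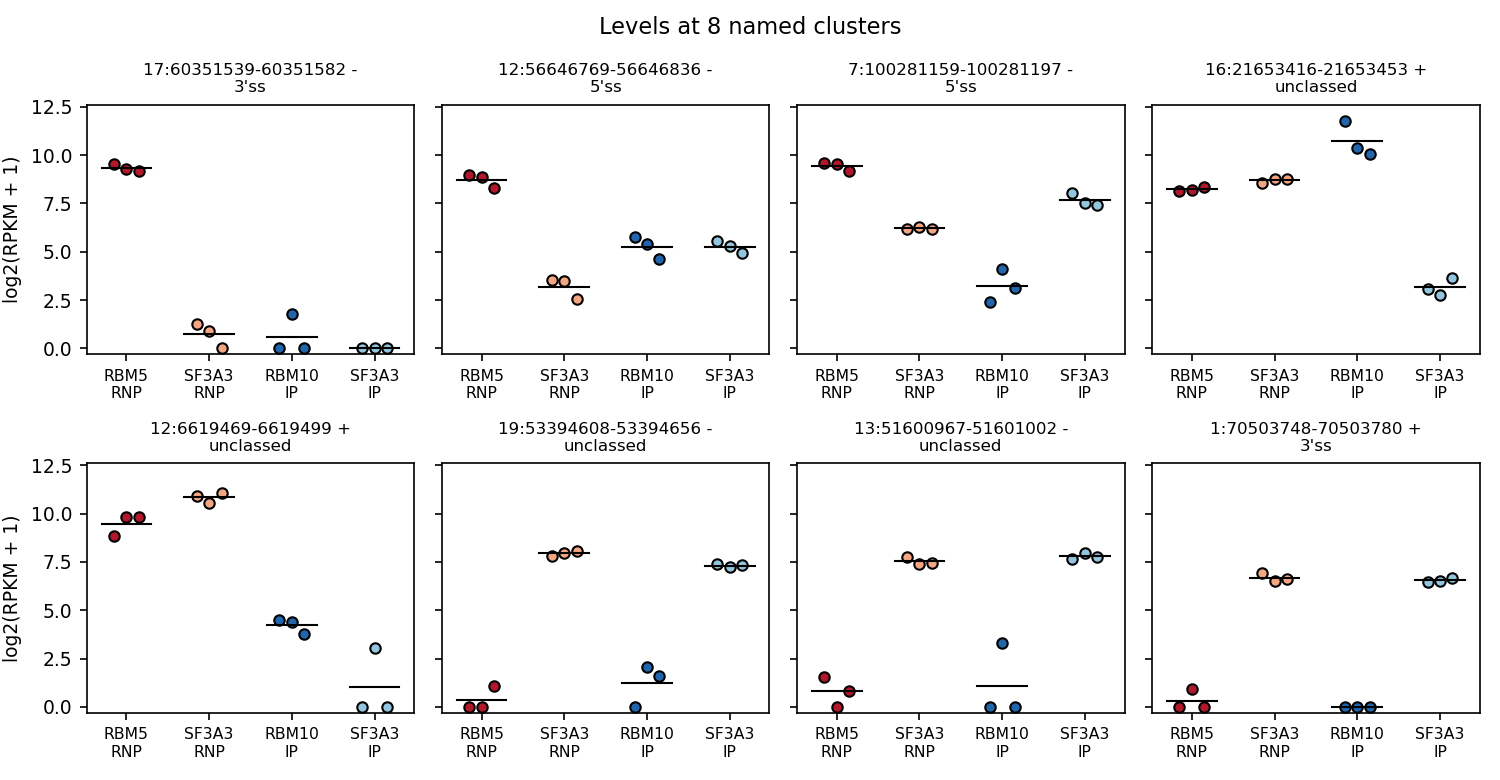
Levels at 8 clusters named in the text (y axis, log2(RPKM + 1)) in the 4 groups (x axis), with hg19 position, strand and class above each panel. Points are single libraries and lines are means of 3. The clusters on chromosomes 19 and 13 and the one at 70503748 on chromosome 1 lie at 8.79 RPKM or lower in each RBM5 and RBM10 library and at 88.4 RPKM or higher in each SF3A3 library.

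SF3A3 complexes differed between the 2 purifications. Comparing SF3A3 RNP-seq with SF3A3 IP-seq asks what the gradient step adds. A pair of neighbouring unclassed clusters on chromosome 12, plus strand, had the largest increases in RNP-seq among clusters of at least 28 nt. The one at 6619469 to 6619499 held 1851 ± 330 RPKM (SD, n = 3) in RNP-seq and 2.38 ± 4.13 in IP-seq, a log2 fold change of 9.83 ± 0.56 (SE, limma adjusted p = 1.77e-08). The one at 6619567 to 6619597 had 2445 reads in RNP-seq and 0 in IP-seq, at least 263-fold higher. With RBM5, also gradient-purified, they held 754 ± 261 and 220 ± 90.5 RPKM, and with RBM10, by direct precipitation, 18.4 ± 4.88 and 4.10 ± 3.61. Lower in RNP-seq were an unclassed cluster on chromosome 1 (145656835 to 145656885, plus strand), at 0.884 ± 0.917 against 30.8 ± 7.32 RPKM, and a 5' splice site cluster on chromosome 12 (10865786 to 10865821, minus strand), with 0 against 15 reads, at least 15.5-fold lower.

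By class, 3' splice site clusters took 73.2% of cluster reads in SF3A3 RNP-seq and 71.0% in IP-seq, and 5' splice site clusters 0.123% and 0.169%, without overlap between libraries (exact permutation p = 0.1 for each, the smallest possible). In all 45634 clusters were higher and 30543 lower in RNP-seq. Without SF3A3 RNP-seq replicate 3 the lower count was 19686. With only the SF3A3 libraries in the fit the counts were 50242 higher and 33500 lower. With voom the balance turned, to 36522 higher and 46533 lower.

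The deposited lists of predicted branch points covered 326871 clusters for RBM5, 212761 for RBM10, and 169903 and 252393 for the first and second SF3A3 list. They held 728615, 476397, 388608 and 586796 points. No cluster marked 5' splice site appeared in any list. Clusters marked 3' splice site made up 41.8% of the RBM5 list, 53.7% of the RBM10 list and 61.2% and 50.5% of the SF3A3 lists. Of the clusters with RPKM values, 151685 were in all 4 lists and 96401 in 1 list only, of which 73387 were in the RBM5 list.

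Predicted branch points lay at similar distances from the edges of their clusters in every list. Clusters marked 3' splice site had a median width of 41 nt. How points were predicted and ranked is not given in the sources used here, so these distances may come from the prediction itself. In 3' splice site clusters the median distance from the best-ranked point to the cluster's 3' end was 16 nt (quartiles 13 and 19) for RBM5, 15 nt for RBM10 and 15 nt in both SF3A3 lists, and the median distance to the 5' end was 23 to 24 nt. In unclassed clusters the medians were 16 to 17 nt and 24 to 25 nt.

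Lists agreed on the exact position for most shared clusters. The best-ranked point was identical in 58.4% (95% interval 58.2 to 58.6) of 190575 clusters shared by RBM5 and RBM10 with a single best point in each. It was identical in 68.3% for RBM5 and the first SF3A3 list, 62.2% for RBM5 and the second, 69.3% and 69.7% for RBM10 and the SF3A3 lists, and 68.6% between the SF3A3 lists. Where RBM5 and RBM10 differed, the median distance was 8 nt. Over all listed points in shared clusters, 61.1% of 528769 RBM5 points were also RBM10 points. Of 382255 points in the first SF3A3 list, 78.3% were in the second. The RBM5 list is longer than the RBM10 list, while the first SF3A3 list is shorter than the second. These 2 shares thus have unlike bases and do not rank the agreement of the pairs. Each list is 1 pooled list, so these differences have no replicate check.

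**Figure D4:**
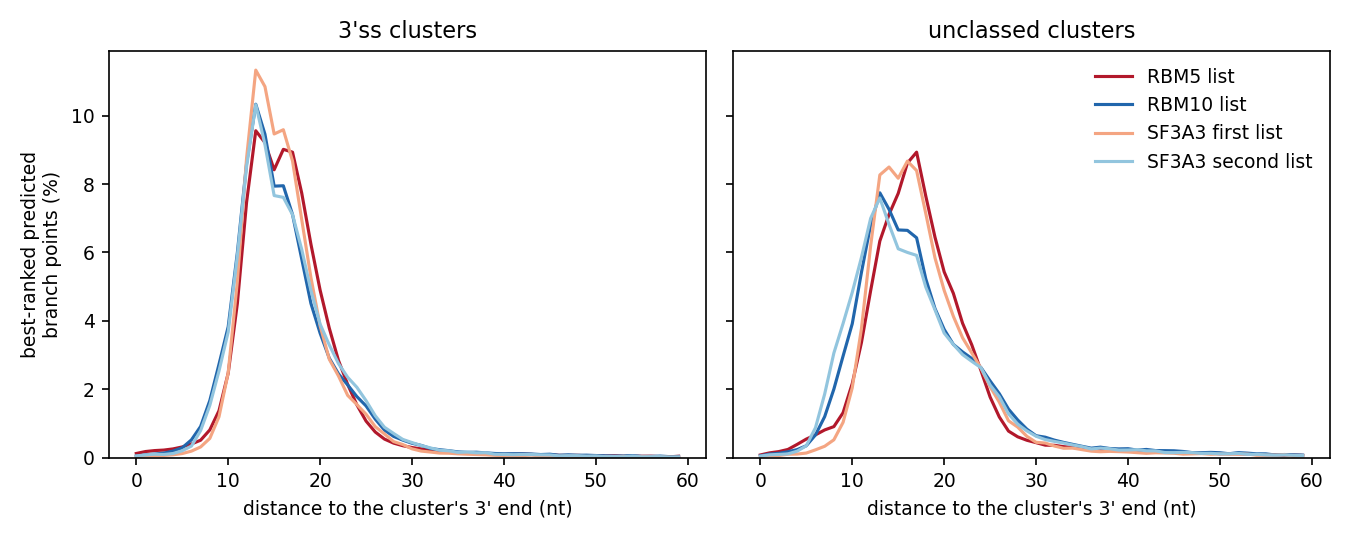
Distance from the best-ranked predicted branch point to the 3' end of its cluster (x axis, nt) against the share of clusters (y axis, percent), for 3'ss clusters and unclassed clusters. Lines are the 4 deposited lists. In 3'ss clusters the medians are 15 to 16 nt in all 4 lists.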

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

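The tests of cluster level and of narrow clusters described here were chosen after the results they bear on had been seen. At 71130 clusters the RBM5 effect over SF3A3 differed from the RBM10 effect over SF3A3, by the interaction test. Of 100 joint splits of the libraries, 2 gave as many called clusters, the real one included, and the highest other gave 99687. These splits remove the effects of both proteins and not only their difference, so they say nothing on whether the difference is due to chance. The highest other exchanges the names of RBM10 and SF3A3 within IP-seq and so adds the effects in place of subtracting them. RBM5 and RBM10 were never profiled by the same assay, so a difference between the proteins cannot be separated from one between purifications by this design.

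Single clusters had a different effect over SF3A3 with RBM5 than with RBM10 by the same test. Here too protein and purification are not separated. The 3' splice site cluster on chromosome 17 (60351539 to 60351582) had an interaction of 8.02 on the log2 scale, with the larger effect for RBM5, and had 2 reads with RBM10 and 0 with SF3A3 in IP-seq. The 5' splice site cluster on chromosome 7 (100281159 to 100281197) had an interaction of 7.69, with opposite directions for RBM5 and RBM10. An unclassed cluster on chromosome X (69670773 to 69670801, plus strand) had -11.25. It held 31.9 ± 23.4 RPKM (SD, n = 3) with RBM5 against 395 ± 48.6 with SF3A3 RNP-seq, and 318 ± 67.0 with RBM10 against 2.16 ± 3.75 with SF3A3 IP-seq. An unclassed cluster on chromosome 1 (146556186 to 146556215, minus strand) had -11.03. It held 23.5 ± 11.5 RPKM with RBM5 against 804 ± 183 with SF3A3 RNP-seq, and 120 ± 17.8 with RBM10 against 2.46 ± 4.27 with SF3A3 IP-seq. At both unclassed clusters the SF3A3 reference differed more between the assays, as a ratio, than RBM5 differed from RBM10.

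For the comparisons of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05. The real split gave as many calls as any in 1 of 10 cases, which is itself. RBM5 against SF3A3 gave 83826 calls and the highest other split 0, RBM10 against SF3A3 gave 81449 and 1, and SF3A3 RNP-seq against IP-seq gave 76177 and 0.

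The larger 5' splice site share with RBM5 and RBM10 did not rest on a few clusters: without the 10 brightest 5' splice site clusters the ratio over SF3A3 was 2.27 for RBM5 and 2.63 for RBM10. A general rise of dim clusters, from background RNA or from regression to the mean, was tested by setting 5' splice site against unclassed clusters within bins of level. With RBM10 the 5' splice site clusters lay higher by at least 0.67 on the log2 scale in all 6 summaries (median over bins, weighted mean and lowest library, each with 2 rankings). That argues against a general rise of dim clusters as the whole cause. By bin the excess ran from 1.94 in the dimmest to -0.19 in bin 9 when ranked by SF3A3, and from 0.58 to 1.77 when ranked by RBM10. Clusters with 0 reads in the ranking library cannot be matched for level. The bins do not test whether dim 5' splice site clusters were found mainly in RBM10 libraries. With RBM5 the summaries were 0.43, -0.27 and 0.29 when ranked by SF3A3 and 0.47, 0.20 and 0.45 when ranked by RBM5. The negative one arose because the dimmest 5' splice site clusters rose less than unclassed ones. Ranked by SF3A3, the excess was -0.87 in bin 1 and -0.20 in bin 2, but 0.20 to 0.69 in bins 3 to 9. Over all bins, a general rise of dim clusters with RBM5 thus cannot be told apart from a difference between the proteins. A candidate explanation for RBM10 is that its complexes hold 5' splice sites more often than SF3A3 complexes do, and no library without a tagged protein was there to test it.

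The higher level of unclassed than of 3' splice site clusters with RBM5 had a difference of medians of 0.65. It was again 0.65 in clusters of at least 28 nt, which decides nothing on narrow clusters, since 226387 of 230918 unclassed clusters are that wide and so few others can hardly move a median. If clusters had been found mainly in RBM5 libraries the difference should nearly vanish among the 151685 clusters in all 4 branch point lists, and it was 0.36 there, between the limits set beforehand, and 0.05 among clusters in the RBM5 list alone (medians 1.10 and 1.05), so this stays open. A general rise of dim clusters stays open too, because the difference was 0.04 with ranking by SF3A3 replicate 1 and 0.52 with ranking by RBM5 replicate 1.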

How the results depend on the processing

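The voom fit, the limit to clusters of at least 28 nt and quantile normalization of class medians were chosen after seeing the data, and the other alternatives before. The cause of the shifts given here was not tested. Fitting only the groups compared moved the RBM5 count from 83826 to 160916 and the RBM10 count from 81449 to 24766, and voom moved the RBM5 count to 151746. All other alternatives left the 4 counts within 1.5 times. The split of calls moved by over 10 points only under voom, for SF3A3 RNP-seq against IP-seq, from 59.9% higher to 44.0%. Smaller moves still turned which direction had more calls in the other 3 comparisons. For RBM5, besides the fits given in the report, it turned without an intensity trend (35649 higher, 33237 lower) and at an absolute log2 fold change of at least 1 (32877, 29298). For RBM10 it turned at a pseudocount of 0.1 (34338, 34701) and among clusters at or above the median mean RPKM (32410, 37151). Leaving out 1 library at a time gave 57653 to 67031 calls for RBM5, 69459 to 87048 for RBM10, 50788 to 70568 between the SF3A3 assays and 52593 to 79821 for the interaction.

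Replicate numbers did not pair the libraries: same-numbered libraries deviated together with r from -0.03 to 0.07. With the number as a replicate block the counts were 84239, 82436, 76305 and 71296. Quantile normalization lowered the median log2 fold change of all clusters from 0.28 to 0.03 for RBM5, from 0.06 to -0.02 for RBM10, from 0.09 to -0.09 between the SF3A3 assays and from 0.15 to 0.05 for the interaction.

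Differences in class shares kept their direction in every alternative run, but not their size. At or above the median mean RPKM the RBM10 differences shrank from 0.265 to 0.074 points (5'ss), from -1.71 to -0.89 (3'ss) and from 1.45 to 0.81 (unclassed, 0.91 without SF3A3 IP-seq replicate 3), and the 5'ss difference between the SF3A3 assays from -0.046 to -0.027. Class medians moved. Among clusters at or above the median mean RPKM, RBM5 medians were -0.24 (3'ss), 0.88 (5'ss) and 0.22 (unclassed), and the RBM10 5'ss median was 0.91. Median-ratio scaling gave -0.10 for RBM5 at 3'ss clusters. Quantile normalization gave -0.006 at 5'ss and 0.15 at unclassed clusters for RBM5, and 1.23 at 5'ss and -0.002 at unclassed clusters for RBM10, where the median was also 0 without RBM10 replicate 2. Voom gave 1.44 for RBM10 at 5'ss clusters. The median of unclassed clusters between the SF3A3 assays, 0.07, turned to -0.22 among those brighter clusters, -0.16 under quantile normalization and -0.37 with voom, and ranged from -0.001 to 0.13 with 1 library left out, falling below 0 without SF3A3 IP-seq replicate 3. The RBM10 median at 3'ss clusters ranged from -0.125 to 0.013, above 0 without RBM10 replicate 1.

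For 34 fold changes of 30 clusters taken by the naming rule, those named in the text among them, the 626 values under alternatives kept direction and call, with limma adjusted p up to 0.0427. The rule took the largest changes that passed the test in these same libraries, so their stability was likely from the start and says little on other called clusters. The size of the named changes moved: the chromosome 17 increase with RBM5 ranged from 5.93 to 10.26, the chromosome 19 decrease from -10.05 to -4.63 and the RBM10 5'ss increase at 97243491 from 2.84 to 9.22. For branch points, allowing 2 nt moved the shared percentages to 64.9 (RBM5 in RBM10), 67.0 and 69.5 (RBM5 in the SF3A3 lists), 75.1 and 80.1 (RBM10 in the SF3A3 lists) and 83.5 (first SF3A3 list in the second). Each is a share of the points of the list named first. Taking the best-ranked point per cluster gave 58.4, 68.3, 62.2, 69.3, 69.7 and 68.6. Not run were all alternatives on gene totals and gene lists, for want of gene names, and a limit by support for branch points, which the lists do not give. The interaction needs all groups, so it has no fit on fewer. Depth limits dim clusters in IP-seq: 9.8 to 30.1% of clusters had 0 reads in an RBM10 library and 18.8 to 28.1% in an SF3A3 IP-seq library.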

Other observations

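The neighbour tests described here were set before their values were seen. The distance classes were chosen after seeing the data. Unclassed clusters close upstream of a 3' splice site cluster had higher medians with RBM10 than those farther away, a difference that was not tested. Among 1982 unclassed clusters 30 to 60 nt upstream of the next 3' splice site cluster on the same strand, centre to centre, 13.3% were higher and 1.7% lower with RBM10, with a median log2 fold change of 0.57. The medians were 0.25, 0.78 and 0.67 for the 3 RBM10 libraries. At 60 to 90 nt the median was 0.51, at 90 to 120 nt 0.43, at 150 to 200 nt 0.16 and at 200 to 300 nt 0.08. Among 63884 unclassed clusters 1000 to 5000 nt upstream, 8.2% were higher and 6.8% lower, with a median of 0.08 and per-library medians of 0.0, 0.30 and 0.0. The median was lowest at 500 to 1000 nt, 0.04, and was 0.13 among 74006 clusters at 5000 to 50000 nt, of which 9.4% were higher and 6.4% lower. Median SF3A3 IP-seq levels differed between these classes, from 3.82 RPKM at 30 to 60 nt through 2.62 RPKM at 120 to 150 nt to 4.33 RPKM at 1000 to 5000 nt, and the classes were not matched for level. With RBM5 the medians fell more slowly, from 0.81 at 30 to 60 nt to 0.74 at 200 to 300 nt and 0.48 at 1000 to 5000 nt, while the share higher was 12.2%, 14.3% and 9.5%.

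Clusters with a change with RBM5 or RBM10 were listed unevenly in the deposited branch point lists. Of 13422 unclassed clusters lower with RBM5, 97.9% were in the second SF3A3 list and 74.6% in the RBM5 list. Of 24219 unclassed clusters higher with RBM5, 96.4% were in the RBM5 list and 43.6% in the second SF3A3 list. The shares for 193277 unclassed clusters without an RBM5 call were 80.7% in the RBM5 list and 52.2% in the second SF3A3 list. Of 20409 unclassed clusters higher with RBM10, 79.7% were in the RBM10 list, 79.3% in the RBM5 list, and 33.2% and 62.6% in the first and second SF3A3 lists. Without an RBM10 call these shares were 37.3%, 81.6%, 24.5% and 50.8%. Which libraries the lists were made from is not stated, so they are not independent evidence.

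Neighbouring clusters tended to share their fold changes. Over pairs of clusters on the same strand within 1000 nt of each other, with a mean above 25 RPKM, the fold changes correlated with r = 0.266 for RBM5 (95% interval 0.218 to 0.305 from resampled chromosomes) and r = 0.354 for RBM10 (0.318 to 0.385). Between 1000 and 20000 nt r was 0.177 and 0.323, and between 100000 and 1000000 nt 0.03 and 0.078. These are correlations across clusters, which are not independent replicates.

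A regional cause such as gene copy number in a cell line should act on both strands alike, but neighbours on opposite strands 1000 to 20000 nt apart correlated at most 0.33 times as strongly as those on the same strand (r = 0.033 for RBM5 and 0.105 for RBM10), which argues against it as the whole cause. Noise shared within a library should vanish when the neighbours are measured in different libraries, and the correlation within 1000 nt kept at least 0.82 times its size. A candidate explanation that remains is a difference in the amounts of whole transcripts between the cell lines, so that every cluster of a transcript moves together. No measurement of total RNA from these lines was used here, so transcript amount and binding were not separated. The clusters on chromosomes 13, 19 and 1 that were low with both RBM5 and RBM10 and high with SF3A3 are open to the same reading. So are increases with RBM5, such as those at 60351539 on chromosome 17 and 133805259 on chromosome 11. Both clusters lay at 2.4 RPKM or lower in every library of the other groups.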
